A study of Mus musculus with 8 samples.

How the data were processed

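Gene expression was measured on 8 Affymetrix arrays, each hybridised with labelled cDNA from the total RNA of 1 mouse cell culture. Whole-transcript kits made and labelled the cDNA, per the labels' protocols, so the probes of a probe set can lie in many exons of a gene. The labels put 4 arrays in a control group, given ethanol, and 4 in a deleted group, given 4-hydroxytamoxifen (4OHT) at 1 µM, and both were collected after 24 h. Each group held 2 biological replicates of each of 2 clones. The deposited table held 35556 probe sets, and its values are probe-set expression levels on the log2 scale. The submitters' processing notes name RMA (robust multi-array average), which corrects background, normalizes between arrays by quantiles and summarises probes by median polish. The version of RMA and the chip definition are not given in the sources used here, and the log base was read from the deposited values, which ran from 2.61 to 13.77 with array medians between 6.26 and 6.39.

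Probe sets were named through the platform annotation supplied with the series. It listed 23410 of the probe sets, of which 21789 had 1 gene symbol and 1621 had several, and 12146 probe sets were not listed and stayed unnamed. Entrez identifiers were looked up in a RefSeq gene table. No symbol changed, and 91 probe sets had an identifier without a match and kept the annotation's symbol. No gene was named from a probe set with several symbols. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was used, which left 19938 genes. No genome was used, so positions of probes and genes were not analysed here.

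Every fit used limma 3.58.1 in R 4.3.3 on the deposited log2 values, with empirical Bayes moderation that lets the prior variance follow mean expression, two-sided tests and Benjamini-Hochberg adjustment over all 19938 genes at a threshold of 0.05. The comparison of deleted with control arrays had the set as a block, a set being the control and the deleted culture of the same clone and replicate number. The series' design text describes 4 sets, from 2 experiments with each of 2 clones. It does not tie the experiments to replicate numbers, so the match of cultures by number was read from the sample titles. The model left 3 residual degrees of freedom per gene, and the moderation added 9.72. Each SE of a difference is the moderated SE of the fit, which borrows spread from other genes, and n = 4 sets beside it counts the sets fitted. It is not the SE of the set differences and can be smaller where a gene's sets disagree. The set differences had an SD of 1.08 for Thbs1, 0.63 for F13a1 and 0.69 for Ms4a3. Within every set, the control and the deleted array deviated together from their group means across genes (r between 0.72 and 0.82), and each control array correlated best with the deleted array of its own set in 4 of 4 sets. After clone means were also removed, these correlations were 0.44 in clone 1 and 0.25 in clone 2. With 2 replicates per clone and group, the deviations of a clone's 2 sets then mirror each other, so each clone gives 1 value. The 4 of 4 sets are therefore not 4 separate results. The effect in each clone and the difference between these effects came from a fit with a separate effect per clone. The clones were compared among control arrays in a fit of 4 cells, clone by group, without the block, because a set lies within 1 clone.

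Gene lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 24 lists. Camera with an estimated correlation and fry were run beside it. The lists cover RUNX and CBFB genes, the MLL fusion and Hoxa program, reported RUNX1 targets, granulocytic, monocytic, progenitor, erythroid, megakaryocyte, mast cell, lymphoid and dendritic cell genes, p53 targets, cell cycle, apoptosis, interferon, inflammatory, sterol, stress, immediate early and MYC genes. Of their 496 distinct genes, 452 were measured by a probe set of their own. Runx2, Trp53 and Cdkn1a were among those not analysed here, for want of such a probe set in the annotation.

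The groups, lists, fits, alternatives and the rule for naming genes were set before the data were examined. The rule names Runx1, Cbfb, Runx2 and Runx3, and the 12 genes per direction with the largest change among those past the threshold that moved the same way in all 4 sets. It also names, per list, up to 4 members past the threshold with the smallest p, or, of a list with none, the 1 member with the smallest p. It always names Trp53, Cdkn1a, Bcl2, Myc, Cebpa, Spi1, Hoxa9, Meis1, Csf1r, Kit and Cd34, and up to 6 genes per direction for the interaction and for the clone difference. Symbols that are only model or clone names were passed over and kept in all counts. Other genes are named in places and are marked as chosen after their values were seen.

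The alternatives set beforehand were 3 other treatments of the pairing, 2 other variance models, array weights, quantile normalization, centring on array medians, leaving out the third of probe sets with the lowest mean, testing all probe sets, averaging a gene's probe sets, comparing the clones in control arrays alone or with a replicate block, and leaving out each set or control array in turn. Cyclic loess normalization, fits within each replicate number and list tests between clones were added after the data had been seen. The fit was tested on simulated data with the 19938 genes and the set structure of the comparison of deleted with control arrays, with 200 genes changed in each of 5 runs. It recovered 43.3% of genes changed by 0.3 on the log2 scale, 91.6% of those changed by 0.5 and 100% of those changed by 1, and 4.75% of its calls were false. With no gene changed it made 0 calls and called 0 lists, and it recovered a list shifted by 0.1 in 5 of 5 runs. The simulated genes varied independently, with spreads drawn from the fit's own prior, and no change shared between sets was simulated. These rates therefore do not carry over to lists whose genes correlate. In the data the estimated correlation was 0.35 for primary granule genes and 0.54 for G2 and mitosis genes. No array held the same values as another in any of the 28 pairs of arrays. The number of arrays limits the precision. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.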

Results

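The series compared mouse MLL-AF9 cells with and without induced deletion of Runx1 and Cbfb. Runx1 encodes a DNA-binding transcription factor of blood cells, and Cbfb encodes the partner protein that RUNX proteins share. MLL-AF9 is a leukaemia fusion protein that keeps myeloid progenitors growing in culture. The cells came from c-Kit-positive marrow of mice with floxed alleles of both genes, and carried MLL-AF9 together with CreERT2, a Cre recombinase that 4-hydroxytamoxifen (4OHT) activates. They were grown in cytokine-containing methylcellulose and given ethanol or 4OHT for 24 h. The 8 arrays covered 2 clones with 2 biological replicates each and formed 4 sets, and every set held 1 control and 1 deleted culture. The fits treat the 4 sets as independent pairs, although they come from 2 clones and same-numbered sets shared part of their change, as given below. Their SE and p-values combine spread between these sets with spread borrowed from other genes. They may be too small where a gene's sets disagree, and for further clones or experiments. Array medians lay between 6.26 and 6.39 on the log2 scale. Correlations across probe sets were 0.991 to 0.997 between arrays of the same clone and 0.977 to 0.991 between arrays of different clones. No culture received 4OHT without carrying the floxed genes, so the effect of 4OHT and active Cre is part of every difference below.

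The targeted genes were examined first. Runx1 signal was higher, not lower, in the arrays labelled deleted: the log2 level was 10.30 ± 0.30 (SD, n = 4) in control arrays and 10.82 ± 0.28 (SD, n = 4) in the arrays labelled deleted. The rise was 1.44-fold (log2 difference 0.52 ± 0.04, SE, n = 4 sets; limma adjusted p = 1.64e-05) and was present in 4 of 4 sets, at 0.53, 0.53, 0.56 and 0.48. Cbfb signal was 9.93 ± 0.08 (SD, n = 4) in control arrays and 9.75 ± 0.13 (SD, n = 4) in the arrays labelled deleted. Its log2 difference of -0.18 ± 0.05 (SE, n = 4 sets) was negative in 4 of 4 sets but did not pass over all genes tested (limma adjusted p = 0.128), although it passed when adjusted over the list alone (0.00394). Runx3, the other RUNX gene with a probe set of its own, had a log2 difference of 0.05 ± 0.04 (SE, n = 4 sets) and did not pass. Each targeted gene had 1 probe set, 10441003 for Runx1 and 10574632 for Cbfb. A whole-transcript probe set averages exons, and probes outside the deleted exons check nothing, so the Runx1 signal went against the label without testing the deletion itself. For that reason the cultures are called labelled deleted, and every direction below follows that label. The Runx1 call ended without the pairing (adjusted p = 1), with clone as the only covariate (0.0617) and with all probe sets tested (0.0567).

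**Figure D1:**
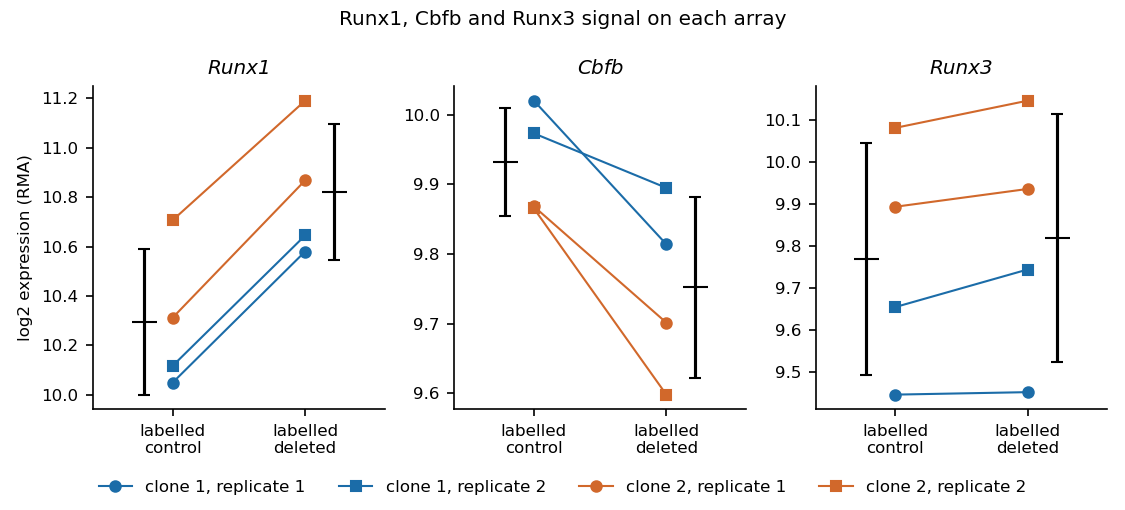
Log2 expression of Runx1, Cbfb and Runx3 on each of the 8 arrays, with lines joining the control and the labelled deleted culture of a set, and black bars for the group mean ± SD (n = 4). Runx1 rose in 4 of 4 sets, the Cbfb values were lower in 4 of 4 sets without passing the test, and Runx3 differed by 0.05; each panel has its own vertical range.

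The first comparison asked which genes differ after 24 h of 4OHT over the 4 sets. In the cultures labelled deleted, 190 of 19938 genes passed, 96 higher and 94 lower, and all 190 moved the same way in 4 of 4 sets. The paired test is made on the same set differences and favours such genes, so this is not separate support. Changes were small, with a median absolute log2 change of 0.38 among the genes that passed. Of these, 32 changed more than 1.5-fold, 16 higher and 16 lower, and 8 more than 2-fold. The count was 0 of 19938 without the pairing in limma (317 genes at an unadjusted p under 0.05), 0 with all 35556 probe sets tested (1834 unadjusted), 13 without the variance trend, 23 with clone as the only covariate, 78 with clone and replicate number as covariates and 388 with array weights, against 1289 unadjusted in the paired fit; without 1 set it was 98 (clone 1, replicate 2), 110 (clone 2, replicate 1) or 418 (clone 2, replicate 2). Within the sets of replicate number 1 it was 192 (139 higher, 53 lower) and within those of replicate number 2 it was 165 (46 higher, 119 lower), in fits chosen after the data were seen.

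Among the genes that rose, Mamdc2, which encodes a secreted matrix proteoglycan, changed most, by 2.63-fold (log2 difference 1.39 ± 0.08, SE, n = 4 sets; adjusted p = 6.47e-06). F13a1, the catalytic subunit of coagulation factor XIII and a gene of monocytes and platelets, rose 2.18-fold (1.12 ± 0.16; adjusted p = 0.00379). The protocadherin gene Pcdh7 rose by 1.08 ± 0.10 and Extl3, a glycosyltransferase of heparan sulfate synthesis, by 1.04 ± 0.09. Ly96, which encodes the MD-2 subunit of the lipopolysaccharide receptor, rose by 0.86 ± 0.10, and Btla, an inhibitory receptor of lymphocytes, rose by 0.77 ± 0.09. Calcrl, the receptor subunit for calcitonin gene-related peptide and adrenomedullin, rose by 0.73 ± 0.08. Ifi209, of the interferon-inducible p200 family, rose by 0.77 ± 0.10, with the reserve that its close paralogs can share probes. The endoplasmic reticulum peroxidase gene Prdx4 rose by 0.82 ± 0.08. Prrg4 rose by 0.67 ± 0.13, Sbf2 by 0.64 ± 0.08 and Hdc, the enzyme that makes histamine, by 0.63 ± 0.06. Adjusted p for these 12 genes ran up to 0.0234, for Prrg4.

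The largest fall was that of Thbs1, which encodes the secreted matrix protein thrombospondin 1. Its log2 level was 9.50 ± 1.59 (SD, n = 4) in control arrays and 7.11 ± 0.58 in the arrays labelled deleted, 5.24-fold lower (log2 difference -2.39 ± 0.27, SE, n = 4 sets; adjusted p = 0.00102). Atp1b1, a subunit of the sodium-potassium pump, was 2.25-fold lower (-1.17 ± 0.14; adjusted p = 0.00130), and Hvcn1, the voltage-gated proton channel of phagocytes, was 2.19-fold lower (-1.13 ± 0.07; adjusted p = 7.59e-06). The myeloid transcription factor gene Cebpa fell by 0.66 ± 0.08, Ms4a3, a membrane protein gene of granulocyte and monocyte progenitors, by 0.81 ± 0.17 (by 0.47 without the set of clone 2, replicate 2, adjusted p = 1.43e-05, its sets ranging from -0.31 to -1.81) and Lilr4b, a gene of the leukocyte immunoglobulin-like receptor family, by 0.88 ± 0.08. Rnase2a, of the eosinophil-associated ribonuclease family, fell by 0.79 ± 0.13. Lilr4b and Rnase2a belong to multigene families whose members can share probes. The engulfment receptor gene Megf10 fell by 0.72 ± 0.09, Bex6 by 0.71 ± 0.08, the cargo receptor gene Tmed3 by 0.67 ± 0.07, Igfbp7, a secreted binding protein for insulin-like growth factors, by 0.62 ± 0.11 and the growth factor receptor gene Pdgfrb by 0.62 ± 0.09. Adjusted p ran up to 0.0484, for Ms4a3. With robust variance moderation F13a1 (adjusted p = 0.559), Thbs1 (0.402), Ms4a3 (0.904) and 2 genes named below, Ngp (0.476) and Spi1 (0.0539), no longer passed.

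**Figure D2:**
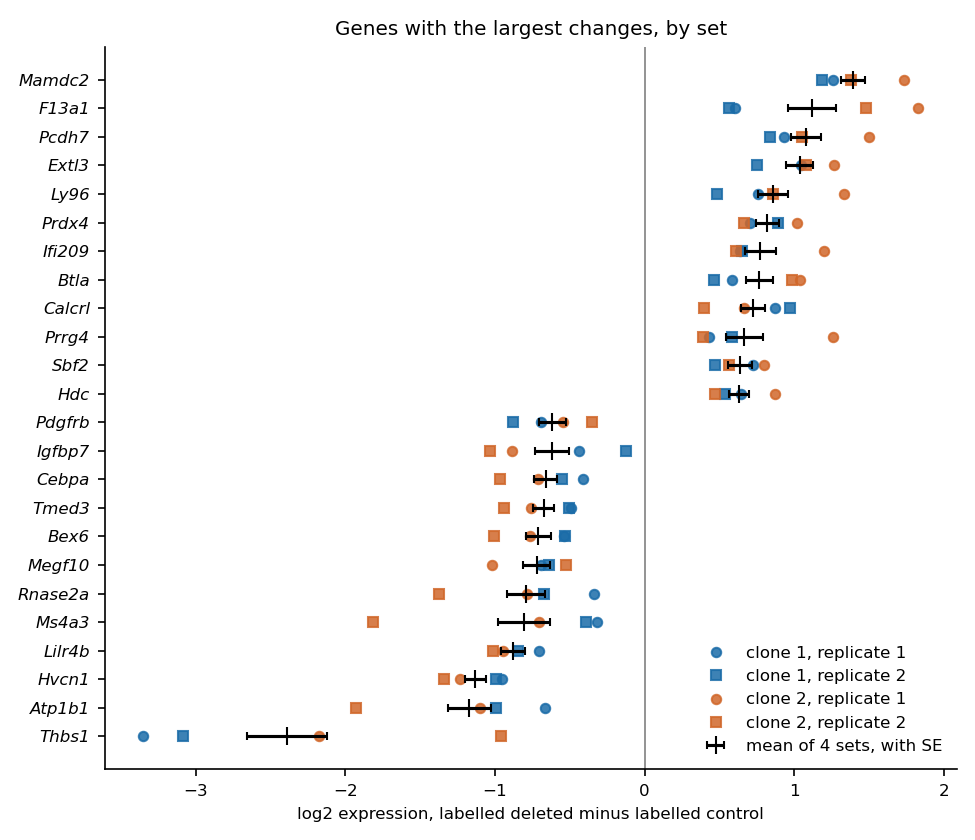
Log2 change, labelled deleted minus labelled control, of the 12 genes that rose most and the 12 that fell most, with 1 point per set. Black bars show the mean over 4 sets ± the moderated SE of the fit. All 24 genes lay on 1 side of 0 in every set because the naming rule required it. F13a1 points were higher in clone 2 than in clone 1, and Thbs1 points ran from -3.35 to -0.96.

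The gene lists put these genes in context. Of 24 lists, 1 was called higher and 6 were called lower by camera. None of the 7 was called with an estimated correlation, where the smallest adjusted p was 0.454, and none by the directional test of fry, whose mixed test called 11 lists as changed in either direction. Of the lists' 452 measured genes, most did not pass singly, and list medians were all under 0.1 in size.

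Reported RUNX1 targets were called lower (median log2 change -0.04 over 22 genes; camera adjusted p = 6.93e-06; adjusted p = 0.454 with an estimated correlation). Of the 22 genes, 6 fell, none rose and 16 did not pass, with the same 6 adjusted over the list alone. Beside Cebpa, they were Kit, the stem cell factor receptor gene (-0.36 ± 0.05, adjusted p = 0.00404), Cebpe, a transcription factor of late granulocyte maturation (-0.34 ± 0.05, adjusted p = 0.00406), and the neutrophil protease gene Prtn3 (-0.15 ± 0.03, adjusted p = 0.0267). The other members were Bcl2, which blocks apoptosis (-0.31 ± 0.06, adjusted p = 0.0429), and Spi1, which encodes the myeloid factor PU.1 (-0.14 ± 0.03, adjusted p = 0.0465). Csf1r, the receptor for macrophage colony-stimulating factor, was at 0.18 ± 0.09 and did not pass. In the RUNX and CBFB list, 1 of 6 measured genes rose (Runx1) and 1 fell, the corepressor gene Cbfa2t3 (-0.35 ± 0.05, adjusted p = 0.00783). Adjusted over the list alone, 1 rose and 2 fell, and camera did not call the list (adjusted p = 0.768). The Cbfa2t3 call ended when the gene's probe sets were averaged (adjusted p = 0.222).

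Primary granule genes were called lower (median -0.08 over 12 genes; camera adjusted p = 2.57e-06; adjusted p = 0.533 with an estimated correlation, and 0.0607 without the pairing). Of them 4 fell, 1 rose and 7 did not pass, and adjusted over the list alone 6 fell and 1 rose. The genes that fell were Ms4a3, Prtn3, the cystatin gene Cst7 (-0.17 ± 0.03) and the granule membrane protein gene Nkg7 (-0.23 ± 0.04), and the one that rose was Hdc. In the late neutrophil list 3 of 21 genes fell and 1 rose, while 6 fell and 2 rose adjusted over the list alone. Camera did not call this list (median -0.03; adjusted p = 0.0869). The 3 that fell were Cebpe, Ngp, a neutrophil granule protein gene (-0.45 ± 0.09), and Itgam, which encodes CD11b (-0.29 ± 0.06), and the receptor gene for granulocyte colony-stimulating factor, Csf3r, rose (0.27 ± 0.05). Adjusted p of these late genes ran up to 0.0316. In the sets of replicate number 1 alone Ngp (-0.20) and Itgam (-0.19) did not pass, and in those of replicate number 2 Ngp was at -0.71.

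p53 targets were the list called higher (median 0.08, mean 0.09 over 31 genes; camera adjusted p = 1.92e-05; adjusted p = 0.533 with an estimated correlation). Of the 31 genes, 25 had a log2 change above 0, and 2 rose, none fell and 29 did not pass; adjusted over the list alone 3 rose. The 2 were Trp53inp1, a p53-induced regulator of cell death and autophagy (0.48 ± 0.09, adjusted p = 0.0312), and Cd80, better known as a costimulatory ligand of T cells (0.41 ± 0.07, adjusted p = 0.0173). Trp53 and Cdkn1a were not analysed here. The list was called in the sets of replicate number 1 alone (adjusted p = 5.95e-06) and not in those of replicate number 2 (0.391).

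A further 4 lists were called lower with few single genes past the threshold. For NF-kB and inflammatory cytokine genes the median was -0.05 over 23 genes (camera adjusted p = 0.00608; adjusted p = 0.454 with an estimated correlation), with 1 that fell, the chemokine gene Ccl3 (-0.19 ± 0.04, adjusted p = 0.0298), and 3 adjusted over the list alone. For sterol synthesis genes the median was -0.05 over 20 genes (0.00325; adjusted p = 0.639 with an estimated correlation), with 1 that fell, the farnesyl diphosphate synthase gene Fdps (-0.19 ± 0.03, adjusted p = 0.0157), and 3 adjusted over the list alone. For S phase genes the median was -0.04 over 29 genes (0.00728; adjusted p = 0.615 with an estimated correlation), and no gene passed in either count, Mcm2 having the smallest p (-0.09 ± 0.03). For amino acid and unfolded protein stress genes the median was -0.03 over 21 genes (0.00853; adjusted p = 0.639 with an estimated correlation), with none past the threshold over all genes and 1 higher and 2 lower adjusted over the list alone; Sdf2l1 had the smallest p (-0.09 ± 0.02). Of the 6 lists called lower, none was called in the sets of replicate number 1 alone, and all but the NF-kB list (adjusted p = 0.0852) were called in those of replicate number 2. Without the set of clone 2, replicate 2, the S phase (0.309), sterol (0.324) and stress (0.510) calls ended, and that of S phase genes also without clone 1, replicate 2 (0.0837), without the variance trend (0.0549), with quantile normalization (0.0565) and with centring (0.0514). The stress call also ended with array weights (0.130) and without the variance trend (0.0686), the stress (0.0587) and sterol (0.0842) calls with clone as the only covariate, and the NF-kB (0.0602), sterol (0.209) and stress calls without the pairing.

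The remaining lists were not called by camera. In the MLL fusion and Hoxa program none of 19 genes passed in either count (camera adjusted p = 0.136), and Pbx3 (0.09 ± 0.03), Hoxa9 (0.03 ± 0.03) and Meis1 (0.04 ± 0.05) did not pass. Of 18 stem and progenitor genes, only Kit passed, while 2 rose and 1 fell adjusted over the list alone (0.532). Cd34 stood at -0.01 ± 0.06. None of 22 monocyte and macrophage genes passed, and 1, Gpnmb (0.32 ± 0.08), was higher adjusted over the list alone (0.223). Of 15 cell cycle inhibitors, Cdkn2c, which encodes the CDK4 and CDK6 inhibitor p18, rose (0.24 ± 0.04, adjusted p = 0.00895), also adjusted over the list alone (0.715). Of 21 BCL2 family and apoptosis regulators, Bcl2 fell, and 1 rose and 1 fell adjusted over the list alone (0.565). None of 29 G2 and mitosis genes passed in either count (0.715), the smallest p being that of Bub1b (0.06 ± 0.04).

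Among signalling and growth lists, none of 26 interferon response genes passed, and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.136); Cmpk2 was at -0.29 ± 0.07. None of 25 immediate early genes passed, with 1 higher and 1 lower adjusted over the list alone (0.779), and Dusp2 was at 0.28 ± 0.07. Their median was above 0 and camera pointed up, while their mean was below 0. None of 25 MYC and ribosome biogenesis genes passed in either count (0.315), Odc1 being at 0.11 ± 0.04 and Myc at 0.05 ± 0.03.

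Lists of other blood lineages were included because cultured marrow can hold such cells. Camera called none, and the mixed test of fry called the mast cell, basophil and eosinophil list (adjusted p = 0.00603) and the B cell list (0.00465). None of 13 erythroid genes passed in either count (camera adjusted p = 0.373), with Car2 at -0.27 ± 0.11. None of 12 megakaryocyte genes passed, and F2r (0.29 ± 0.08) was the 1 gene higher adjusted over the list alone (0.296). Of 19 mast cell, basophil and eosinophil genes, Hdc rose and Ccl3 fell, and 1 rose and 2 fell adjusted over the list alone (0.264). Both genes are also in other lists. Of 15 B cell genes, the scaffold protein gene Bank1 rose (0.63 ± 0.08, adjusted p = 0.00187), also adjusted over the list alone, and camera did not call the list (0.550). Its median was below 0, while its mean and the camera direction were above 0. None of 17 T and NK cell genes passed in either count (0.315), with Cd2 at -0.16 ± 0.08. None of 18 dendritic cell and MHC class II genes passed over all genes or adjusted over the list alone (0.157), and Flt3 was at 0.29 ± 0.09.

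**Figure D3:**
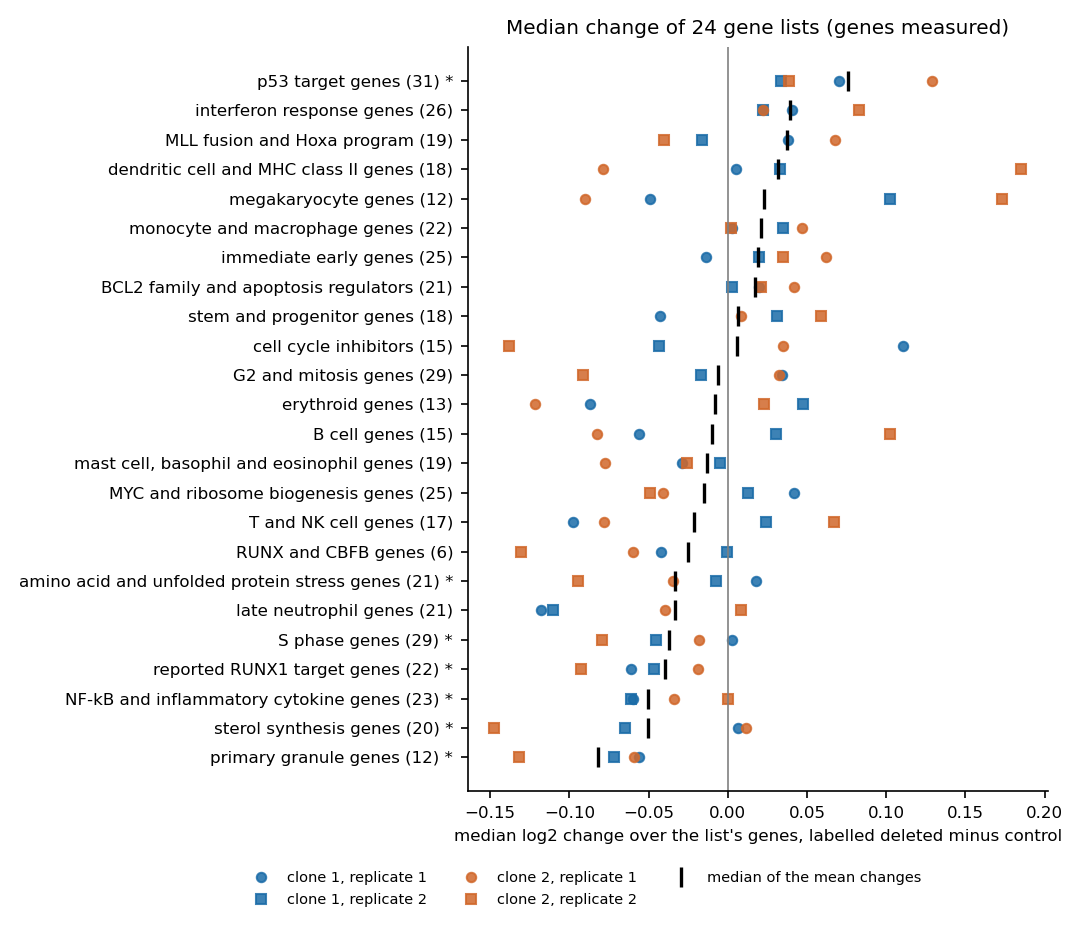
Median log2 change, labelled deleted minus labelled control, over the measured genes of each of 24 lists, with 1 point per set, a black mark for the median of the genes' mean changes, and the number of genes in brackets. Stars mark the 7 lists that camera called at a preset correlation, none of which was called with an estimated correlation; the p53 median of 0.08 is the highest and the primary granule median of -0.08 the lowest.

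The second question was whether the change is shared by the clones. With an effect fitted per clone, 36 genes passed in clone 1 (12 higher, 24 lower) and 136 in clone 2 (57 higher, 79 lower). Of these, 27 passed in both, and no gene passed in opposite directions. Of the 27, 12 rose and 15 fell. Mamdc2 rose by 1.23 ± 0.10 in clone 1 and 1.56 ± 0.10 in clone 2 (SE), Runx1 rose by 0.53 ± 0.06 and 0.52 ± 0.06, and Hvcn1 fell by 0.97 ± 0.09 and 1.29 ± 0.09. Thbs1 fell by 3.22 ± 0.19 in clone 1, or 9.29-fold, and by 1.56 ± 0.19 in clone 2, or 2.96-fold, from control levels of 10.79 and 8.20. Its sets in clone 2 were apart, at -2.17 and -0.96. Of the genes that passed in clone 1, 34 of 36 had the same sign in clone 2, and of those that passed in clone 2, 131 of 136 had the same sign in clone 1. Across all genes, which are not independent replicates, the clones' changes correlated with r = 0.28. This rested on sets of the same replicate number, which correlated between clones at 0.45 and 0.31, against 0.14 and -0.23 for sets of different numbers, so a shared experiment and a shared effect are not separated by it. The 2 sets of the same clone correlated at only 0.08 in clone 1 and -0.13 in clone 2, so replicates of a clone agreed little across all genes. In clone 1 limma called 0 genes with all probe sets (1236 unadjusted), 0 without the variance trend (601) and 1 without the pairing, but 175 with array weights, 61 with quantile normalization and 59 with centring. In clone 2 it called 0 (1269 unadjusted), 3 and 4, and leaving out a set gave 25 to 256 genes in clone 1 (255 and 256 without replicate 2 or 1 of clone 2) and 161 to 665 in clone 2 (266 and 665 without replicate 2 or 1 of clone 2).

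The difference between the clones' effects passed for 2 genes, with 393 at an unadjusted p under 0.05. F13a1 rose by 0.59 ± 0.08 in clone 1 and by 1.66 ± 0.08 in clone 2, a difference of 1.07 ± 0.11 (SE; adjusted p = 0.00201), and its control level was higher in clone 1 (10.04) than in clone 2 (8.46). Ly6a2, a gene of the Ly6 family of surface proteins, was at -0.22 ± 0.06 in clone 1, where it did not pass, and fell 2.00-fold in clone 2, a difference of -0.78 ± 0.09 (adjusted p = 0.00276). Family members of Ly6a2 can share its probes. For Thbs1 the difference of 1.65 ± 0.26 did not pass (adjusted p = 0.0750). Both calls ended without the pairing, without the variance trend and with all probe sets, where limma called 0 genes (178, 304 and 776 unadjusted), and the count was 12 with centring, 4 with array weights and 5, 13, 224 or 40 when a set was left out (clone 1 replicate 1 and 2, then clone 2 replicate 1 and 2).

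The last comparison set the clones against each other in control cultures, to show the size of clone differences beside the change after 4OHT. Each side is 1 clone with 2 control cultures, so the p-values here rest on spread between cultures, partly borrowed from other genes, and compare this pair of clones only. Between clones 792 genes passed, 320 higher and 472 lower in clone 2, of which 564 differed more than 1.5-fold and 259 more than 2-fold. The median absolute log2 difference of these genes was 0.75. Cd34, a surface marker of haematopoietic progenitors, was at a log2 level of 5.85 in clone 1 and 11.33 in clone 2 (adjusted p = 3.19e-08). Xist, the RNA that coats the inactive X chromosome, was at 5.11 and 11.21, and the Y-linked genes Eif2s3y and Uty were at 9.44 and 9.02 in clone 1 and at 4.23 and 4.09 in clone 2. Such levels point to male cells in clone 1 and female cells in clone 2, so sex and source animal cannot be told apart from other clone differences. Also higher in clone 2 were Lin28b, an RNA-binding repressor of let-7 maturation (5.37 and 9.45), the uridylyl transferase gene Tut4 (5.49 and 9.93), Taf9b (4.85 and 9.94) and Bmpr1a, a receptor for bone morphogenetic proteins (5.48 and 9.43). Lower in clone 2 were Eya1, a transcriptional coactivator and phosphatase (11.02 and 5.30), the retinol carrier gene Rbp4 (11.02 in clone 1), Tbc1d19 (8.49 and 4.42) and the histone variant gene Macroh2a2 (9.13 and 5.10). The lower level of each of these genes lay below all 8 array medians, except that of Rbp4, which lay among them, and no level was tested against background, so no fold is given. Adjusted p for these 12 genes ran up to 1.80e-04, for Bmpr1a. The count was 477 with all probe sets, 1241 from control arrays alone, 1330 with the replicate number as a block, and 352 and 409 without control replicate 1 or 2 of clone 1 and 461 and 394 without those of clone 2.

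**Figure D4:**
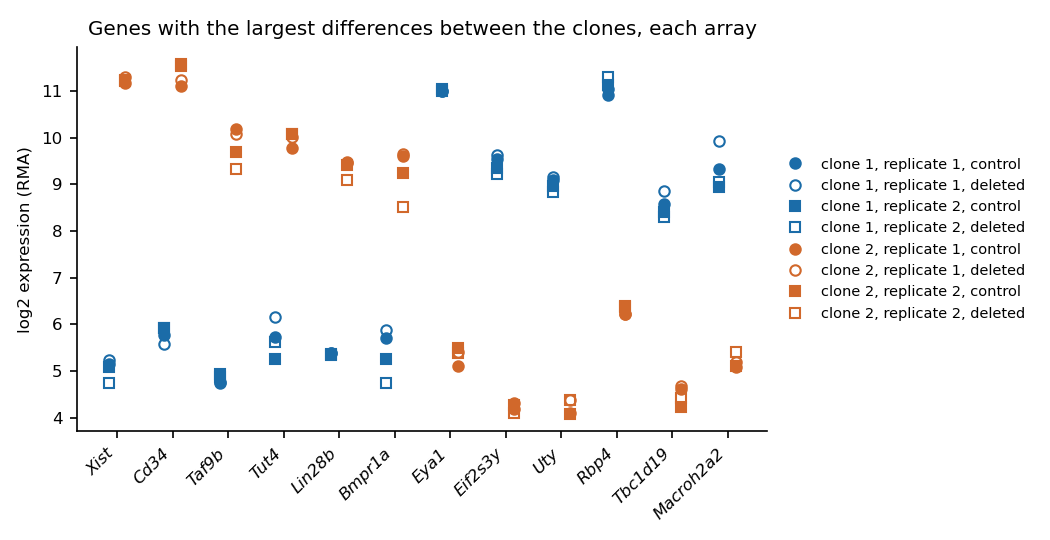
Log2 expression on each of the 8 arrays of the 6 genes most above and the 6 most below in clone 2 relative to clone 1, with filled points for control and open points for labelled deleted cultures. The clones are apart for all 12 genes, as for Cd34 at 5.85 and 11.33. Both cultures of a set lie closer to each other than to the other clone, though Bmpr1a in clone 2, replicate 2 was at 9.25 (control) and 8.52 (labelled deleted).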

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

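None of the tests in this part was chosen after its result was seen. The 190 genes that passed in the labelled comparison stand beside 0 in each of the other 7 of the 8 splits that part all 4 pairs, and only 1 of these 8 splits, the labelled one, gave as many. The smallest share that 8 splits can give is 0.125, so they are too few for a share under 0.05. In the other 7, some set differences change sign, so a change shared by the sets goes into the residual. Few calls are then likely, and their 0 calls do not measure what would be called without an effect. Of the remaining 27 of 35 splits, 24 part 2 pairs and called between 0 and 7 genes, and 3 part no pair and could not be fitted with the pairing.

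In 4 of 122 groups of 4 arrays tested for the named genes, 1 array lay far from the other arrays of its group, and chance gives about 1 in 20 for arrays of 1 population. Each group holds both clones, so that rate is only a rough guide here. Sbf2 stood at 8.13 in the labelled deleted culture of clone 1, replicate 1. Hdc stood at 9.41 in the control culture of clone 2, replicate 2. Car2 stood at 5.81 in the labelled deleted culture of clone 2, replicate 1, and Cd2 at 5.04 in the control culture of clone 2, replicate 1. The 4 cases fell on 4 different arrays, and Car2 and Cd2 did not pass in the comparison itself.

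The clones' effects differed by the interaction test for 2 genes. F13a1 rose in both clones, by 1.07 more on the log2 scale in clone 2. Ly6a2 was at -0.78 in clone 2 relative to clone 1. Among the 13767 probe sets without a single gene name, limma called 0 when all 35556 probe sets were tested together (1834 of all at an unadjusted p under 0.05).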

How the results depend on the processing

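Cyclic loess and the fits within a replicate number were chosen after the data had been seen. Unless a reason is given, the cause was not tested. Without the pairing, limma called 0 genes for the labelled deletion (190 in the paired fit), 1 in clone 1 (36), 4 in clone 2 (136) and 0 for the interaction (2), camera called 3 lists (7), and Runx1 kept its difference of 0.52 with an adjusted p of 1. Clone as the only covariate gave 23 genes and left Runx1 (0.52) at an adjusted p of 0.0617, and clone with replicate number gave 78. These fits leave differences between sets in the residual. Without the variance trend the counts were 13, 0 in clone 1, 3 in clone 2 and 0 for the interaction. Array weights gave 388, 175 in clone 1 and 4 for the interaction. Quantile normalization gave 61 in clone 1, and centring gave 59 in clone 1 and 12 for the interaction. With all 35556 probe sets, limma called 0, 0 and 0 genes for the deletion and both clones, 0 for the interaction and 477 between clones (792), and Runx1 (0.52) had an adjusted p of 0.0567. The prior degrees of freedom were then 3.33 rather than 9.72. Between clones, control arrays alone gave 1241 and the replicate block 1330. Camera with an estimated correlation and the directional test of fry each called 0 lists.

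Leaving out a set gave 98 to 418 genes for the deletion (98 without clone 1 replicate 2, 418 without clone 2 replicate 2), 25 to 256 in clone 1, 161 to 665 in clone 2, 5 to 224 for the interaction and 4 to 9 lists. Leaving out a control array gave 352 to 461 genes between clones. A clone left with 1 set is assumed to vary like the other. In the sets of replicate number 1 alone 3 lists were called, and S phase genes (adjusted p = 0.947) and sterol synthesis genes (0.794) pointed up without passing. In those of replicate number 2 alone, Meis1 was at -0.0454 and Cd34 at 0.00745, both reversed, and neither passed in any fit named here. Cd34 ranged from -0.0587 to 0.0461 when a set was left out, the highest without clone 1 replicate 1.

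Of 41 named genes that passed, without Runx1 and without Ly6a2, which was named for the interaction, none turned direction under any alternative run. All 41 moved the same way in every set, so leaving out or weighting sets could not turn a direction. The pairing and variance alternatives leave the difference itself unchanged. Only another scaling or averaged probe sets could have turned a direction. With array weights or without the dimmest probe sets 41 passed, with quantile normalization 40, with cyclic loess 38, with robust moderation 36, with centring 31, within either replicate number 30, without 1 set 27 to 41, with clone as the only covariate 11 and with replicate number added 26, with averaged probe sets 40, without the variance trend 8, and without the pairing or with all probe sets 0. Calls that ended without clone 1 replicate 1 were those of Prtn3, Csf3r, Ngp, Itgam, Cd80, Trp53inp1 and Spi1. Without clone 1 replicate 2 they were Prrg4, Pdgfrb, Cbfa2t3, Prtn3, Cst7, Nkg7, Csf3r, Ngp, Itgam, Cd80, Cdkn2c, Bcl2, Fdps and Spi1, and without clone 2 replicate 1 Prrg4, Igfbp7, Csf3r, Cd80, Trp53inp1, Bcl2 and Ccl3. Their adjusted p then ran from 0.0523 to 0.430. Lists were not run with robust moderation, which camera does not offer. The 3 other scalings moved the median of all genes little, most with centring (-0.0226). Yet the change varied with expression level. In clone 2, replicate 2 the median change was 0.0774 among the dimmest genes and -0.0752 among the brightest. The brightest were at 0.0470 and 0.0185 in the replicate 1 sets, and at -0.0066 in clone 1, replicate 2. Random lists matched on expression were not drawn for the 6 lists called lower, so the part of this trend there was not tested. With cyclic loess the S phase (camera adjusted p = 0.0154), sterol (0.00514) and stress (0.0321) calls stayed.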

Other observations

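Chosen after the results were seen were the genes named in the next paragraph, the list tests between clones, the tests of replicate number other than the correlations after a loess and by expression level, the setting of these beside the other pairs of sets and their repeat without the dimmest genes, the scaling and label tests for Runx1, and the tests of 4OHT and of single sets for p53 targets.

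Of the 27 genes that passed in both clones, 16 are named in the comparisons, and some of the others follow. Sema4a, a semaphorin gene of immune cells, fell by 0.58, and the NADPH oxidase subunit gene Ncf1 and the interferon-inducible gene Ifitm1 fell by 0.47 each. The activation marker gene Cd69 and Serpinb1a, an inhibitor of neutrophil proteases, fell by 0.45 each, with the reserve that Serpinb1a has close paralogs. Sgsh, a lysosomal sulfatase gene, rose by 0.49, and the fatty acid elongase gene Elovl6 rose by 0.37. Vcam1, an adhesion molecule gene, passed over the 4 sets with a fall of 0.54.

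Between clones in control cultures camera called 8 of 24 lists, and 0 with an estimated correlation. Sterol synthesis genes were lower in clone 2 (median log2 difference -0.35; adjusted p = 4.90e-07), and stem and progenitor genes were higher (median 0.21; 3.90e-08), with Cd34, Erg, Etv6, Flt3 and Lmo2 past the threshold. Reported RUNX1 targets and immediate early genes were called higher in clone 2, and p53 targets, G2 and mitosis genes, cell cycle inhibitors and stress genes lower. The clones' effects differed by camera for 3 lists: late neutrophil genes (higher in clone 2; adjusted p = 4.44e-05), stress genes (lower; 0.00344) and MYC and ribosome genes (lower; 0.0166), each with an adjusted p of 0.859 with an estimated correlation, under which 0 lists were called.

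Runx1 signal rose by 0.52 in cultures labelled deleted. An array-wide scaling shift is argued against, since the smallest Runx1 difference over 3 other scalings was 0.50. Control and deleted labels exchanged in all sets could give a rise, but Cbfb was at -0.18, the direction of the labels, without passing over all genes, so this stays open. Transcription of a deleted allele, with probes outside the deleted exons, may also give a rise, and no probe-level values were analysed here to test it.

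Sets with the same replicate number shared part of their change. Across genes, the changes of same-numbered sets of different clones correlated at a mean r of 0.38, against -0.03 for the other pairs of sets. Those other pairs include the 2 sets of the same clone, at 0.08 in clone 1 and -0.13 in clone 2. A trend with expression level is argued against as the whole cause, since the mean r was 0.33 (other pairs 0.07) after a loess on mean expression. Noise of dim probe sets is argued against as the whole cause. The mean r was 0.51 among the third of genes with the highest mean expression, where other pairs also reached 0.34, and 0.12 among the third with the lowest. Without these dimmest genes the same-numbered pairs had r of 0.39 and 0.53, above the highest of the other pairs, 0.22. Cultures handled together may share such a change, and the series' design text names 2 experiments without tying them to replicate numbers. The interaction with replicate number passed for 0 genes in limma, with a smallest adjusted p of 0.0577. At an unadjusted p under 0.05 it had 3589 genes, 18.0% of those tested, so 0 calls do not show its absence. In the same fit the labelled deletion had 2790 such genes in replicate number 1 and 2698 in replicate number 2. The 1289 of the main paired fit came from a model that leaves differences between replicate numbers in the residual. Camera called 7 lists for the interaction with replicate number, p53 targets among them (adjusted p = 0.0204), 0 with an estimated correlation.

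p53 targets were called higher as a list at the preset correlation, with a median of 0.08, but not with an estimated correlation (camera adjusted p = 0.533). Their expression level as the cause is argued against: the median lay at percentile 100 of 10000 random lists matched on mean expression, whose highest was 0.06. An effect of 4OHT or of active CreERT2 rather than loss of the genes cannot be told apart from the label, since 0 arrays came from cells given 4OHT without deletion, and Cre cutting of DNA could act on p53. A change in one experiment only also stays open, as the lowest of the 4 sets' medians was 0.0337, with an SE of 0.02 over 31 genes. Loss of the genes remains among the open explanations.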
